A study of Rattus norvegicus with 12 samples.

How the data were processed

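Messenger RNA of the posterior colliculus, the auditory part of the midbrain roof, was measured in 6 male Fischer 344 rats that inhaled carbonyl sulfide (COS). The labels give 500 ppm for 6 h a day on 1 day (3 rats, animals 2, 3 and 9) or on 2 consecutive days (3 rats, animals 6, 16 and 19), with tissue taken directly after the last exposure. Each rat was compared with a pool of RNA from rats in filtered air, on a pair of Agilent rat oligonucleotide arrays with the dyes exchanged, so 12 arrays with 2 channels each were analysed. The labels count days from 0 and call the groups day 0 and day 1, and they name a control pool for each day. The protocol counts 3 control animals in all, so whether the 2 pools hold RNA of the same rats is not given in the sources used here.

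The deposited scanner tables hold spot intensity values in both channels, extracted from the scans by the authors with Agilent Feature Extraction 8.1 at default settings, per the labels' protocols. Per the file headers the program was version 8.1.1.1. The same tables hold a log10 ratio of Cy5 over Cy3 per spot, made by that program from background-subtracted and dye-normalized signals, per the file headers. The labels' protocols name Rosetta Resolver 6.0 as the system into which the values were loaded. The deposited series matrix holds log2 ratios. Set against the scanner tables, its values equal the program's ratio turned to exposed over control, to within 0.0001 on the log2 scale for nearly all probes of each array. Its columns have medians between -0.0001 and 0.0025, so neither its scale, direction nor centring stays unknown.

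From the scanner tables, mean spot signals were corrected with limma's normexp method on the local median background, with an offset of 50, and normalized by loess within each array, with control spots at weight 0. Spots that the scanner program marked as outliers were treated as missing, and control spots were left out. Each array's log2 ratio was turned to exposed over control pool. The 2 arrays of a rat were averaged to 1 value, which cancels a constant dye effect, and a rat lacking either array's value for a probe had none. Probes were kept where at least 1 channel was well above background on at least 6 of the 12 arrays and at least 2 rats per group had a value, which left 20195 of 20500 probes. Because the offset shrinks ratios of dim probes, log2 ratios by the scanner program are given where those of dim genes that passed moved by more than 1.5 times. Over the probes that passed the test the program's ratios had a median of 1.12 times the size used here, with the same sign for all of them.

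A linear model (limma lmFit and eBayes) was fitted to the 6 rats' values with both groups in one fit, which share 1 estimate of spread. Each group mean was tested against 0, and the contrast of the group means tested 2 days against 1 day. P-values were adjusted by Benjamini-Hochberg over all probes, with a threshold of 0.05. No control rat was hybridised alone, so these tests leave out the spread between control rats. For 36 gene lists with at least 5 measured genes, fixed before the data were examined, limma's camera was run with a preset correlation of 0.01, with an estimated correlation beside it, and limma's fry gave a self-contained test. Beside each list's counts over all probes stands the count adjusted over the list alone. Probes were named through the RefSeq-based table of assembly GRCr8: 4931 by RefSeq accession, 4257 by Entrez number, 645 by symbol and 183 by synonym. Another 816 kept the name in the scanner files and 9668 had no gene symbol. A gene was represented by its brightest probe, which gave 8950 named genes. No coordinates are given because no genome was used here.

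Genes named in the text follow a rule fixed before the data were examined. For each exposure comparison it takes the 8 largest and 8 smallest mean log2 ratios among named genes that passed with all rats and both dye orientations going the same way. It adds the 3 members with the smallest p of each list that passed, and a fixed set of genes whether they passed or not. For 2 days against 1 day up to 5 were taken from each end. Of that fixed set Cdkn1a and Per1 were not analysed here, and 1 measured gene is not reported here. Other list members are named to complete counts or as examples, and were chosen after their values were seen.

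The fit was tested on simulated rats with 200 changed probes per group among 20195. At a log2 change of 0.3, it recovered 89.6% of them for 1 day, 92.5% for 2 days and 72.9% for 2 days against 1 day. At 0.6 it recovered 100%, 98.5% and 96.9%, and at a log2 change of 1 it recovered 100% in each. It called 11, 7 and 14 unchanged probes. With 3 lists shifted by 0.1, camera called 3 for 2 days and 2 for 2 days against 1 day, 2 of 3 in both with an estimated correlation, and no other list. The simulated probes were drawn independently of each other and without any deviation of a control pool. False calls from genes that move together or from a pool's own deviation were therefore not covered by this test.

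Alternatives in the first steps, fixed before the data were examined, were no background subtraction, normexp with an offset of 0, the program's log ratio, the series matrix, median centring and Aquantile normalization between arrays. Others were looser and stricter filters on dim probes, outlier spots kept, all 12 arrays with the rat as a random block with or without a dye term, each group fitted alone, each dye orientation alone and each rat left out in turn. One was chosen after seeing the data: each exposed rat against the control pool of the other day, from single channels after loess and Aquantile. All arrays were scanned on the same day, 1 array per slide, and the slide numbers of the groups lie in separate ranges, so slide lot and group cannot be told apart. Computations used R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table, and Python 3.11.15 with matplotlib 3.10.9.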

Results

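Carbonyl sulfide is a toxic gas that carbonic anhydrase converts to hydrogen sulfide. The series addresses its neurotoxicity through gene expression in the posterior colliculus of rats after 1 day or 2 days of inhalation at 500 ppm for 6 h a day. Each group held 3 exposed rats, and each rat was measured on 2 dye-exchanged arrays against the filtered-air control pool of its day. Per array and channel, 93.5% to 98.8% of probes were well above background and at most 4 were saturated, and the number of arrays limits the precision. Ratios below are log2 of exposed over control pool, as the mean over rats ± SD, from the limma fit to 20195 probes.

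The first question was which transcripts differed from the control pool after a single day of exposure. The largest rise was in Klf4, a zinc finger transcription factor, at 2.41-fold (log2 1.27 ± 0.07, n = 3, adjusted p = 0.00018). Ccn1, a secreted matrix-associated signalling protein, rose 2.08-fold (1.06 ± 0.27, adjusted p = 0.0030), and Adamts1, a secreted metalloprotease, rose 1.64-fold (0.72 ± 0.08, adjusted p = 0.00018). By the scanner program's ratios Ccn1 rose most (1.88), above Klf4 (1.53). The largest fall was in Hspa1a, the inducible heat shock protein of the Hsp70 family, which was at 0.451 of the pool's level (log2 -1.15 ± 0.05, adjusted p = 2.1e-05). In all, 809 probes passed, 452 higher and 357 lower, and among 8950 named genes 226 rose and 112 fell. Most of these changes were small: the median size over passing probes was 0.19, and only 11 rose and 3 fell by more than 1.5-fold.

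Among the other largest rises after 1 day, Thbd, the thrombin receptor thrombomodulin of endothelium, rose by 0.59 ± 0.08 (adjusted p = 0.0012), and Oxt, the oxytocin precursor, rose by 0.58 ± 0.15 (adjusted p = 0.015). Dst, which encodes the cytoskeletal linker dystonin, rose by 0.56 ± 0.04, Nfx1 by 0.62 ± 0.13 and Lrrc32, a cell surface anchor of latent TGF-beta, by 0.61 ± 0.09 (2 rats). Only 2 of the 8 Dst probes and 1 of the 2 probes of each of Nfx1, Lrrc32 and Thbd passed, the other Thbd probe lying at -0.07 ± 0.05. The values of Oxt, Nfx1 and Lrrc32 ran alike across rats, and whether they are separate signals was not tested. Of the genes that fell, Slc7a3 and Slc38a2, transporters of cationic and small neutral amino acids, had log2 ratios of -0.53 ± 0.03 and -0.36 ± 0.15. Prph, the neuronal intermediate filament peripherin, stood at -0.68 ± 0.32, Ankrd37 at -0.55 ± 0.03, the splicing factor kinase Clk1 at -0.42 ± 0.11, LOC297999 at -0.41 ± 0.10 and Ret, the receptor of GDNF family ligands, at -0.36 ± 0.10, each past the threshold. By the scanner program's ratios the dim gene Thbd rose by 1.53.

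Among the fixed lists, immediate early genes had the most members that rose after 1 day with adjustment over all probes. Of 24 measured, 5 rose and 0 fell, against 6 and 1 adjusted over the list alone. By that second count, vascular tone and vessel mediators also had 6 that rose. Beside Klf4, the rises of immediate early genes were in Atf3 (0.54 ± 0.03, or 1.45 by the scanner program's ratio), Ier2 (0.54 ± 0.05), Klf6 (0.44 ± 0.04) and Btg2 (0.42 ± 0.14), all transcription factors or regulators induced within minutes to hours by many stimuli. Fos (-0.08 ± 0.38, adjusted p = 0.777) and Egr1 (-0.51 ± 0.36, adjusted p = 0.061) did not pass. As a set the immediate early genes had a camera adjusted p of 0.0564, and adjusted p = 0.754 with an estimated correlation. Heat shock proteins had the same camera adjusted p of 0.0564 downward (adjusted p = 0.754 with an estimated correlation). Of 14 measured, Hspa1a was the 1 that fell and 0 rose (2 and 0 adjusted over the list alone). Cytochrome c oxidase subunits also had an adjusted p of 0.0564, upward (adjusted p = 0.754 with an estimated correlation), while 0 of 14 changed (3 rose and 1 fell adjusted over the list alone). Of 26 oxidative stress and Nrf2 genes, 3 rose and 0 fell, the same counts adjusted over the list alone: Nfe2l2, the gene of Nrf2 itself (0.18 ± 0.06), Nqo1 (0.16 ± 0.04) and Tkt (0.13 ± 0.01).

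No list passed for 1 day by camera, where 7 of 36 had an unadjusted p under 0.05, and none did with an estimated correlation, where 1 had. By fry, 2 of 36 moved on balance one way at the adjusted threshold and 24 changed in either direction. Of the 13 measured genes of the fixed set, Hspa1a passed and 12 did not. Beside Fos and Egr1, those included Vegfa (-0.06 ± 0.04), Nos1 (-0.01 ± 0.08), Ptgs2 (-0.03 ± 0.07), Hmox1 (-0.04 ± 0.02), Il1b (0.06 ± 0.12), Cox4i1 (0.01 ± 0.07), Gadd45b (0.05 ± 0.08), Gfap (-0.03 ± 0.10) and Fkbp5 (-0.18 ± 0.12, adjusted p = 0.064). The number of passing probes was 112, 57 or 169 without animal 2, 3 or 9 and 469 without animal 6 of the other group. The genes LOC297999, Lrrc32, Nfe2l2, Nfx1, Nqo1, Oxt, Prph, Slc38a2, Slc7a3 and Tgm2 lost their calls when at least 1 of animals 2, 3, 9, 6 and 19 was left out, at adjusted p values between 0.0509 and 0.170. Against the control pool of the other day, an alternative chosen after seeing the data, 638 probes passed, 230 of them among the 809, and 6 named genes that had passed missed the threshold, at adjusted p values between 0.0512 and 0.19. The ratios of Atf3 (0.277), LOC297999 (-0.254) and Slc7a3 (-0.391) were smaller there, while those of Nes (0.329 against 0.326, or 0.664 by the program's ratios against its own day's pool), Nqo1 (0.187) and Tgm2 (0.316) were not. With the scanner program's ratios 367 probes passed, 243 higher and 124 lower, a share of 66.2% higher against 55.9%.

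**Figure D1:**
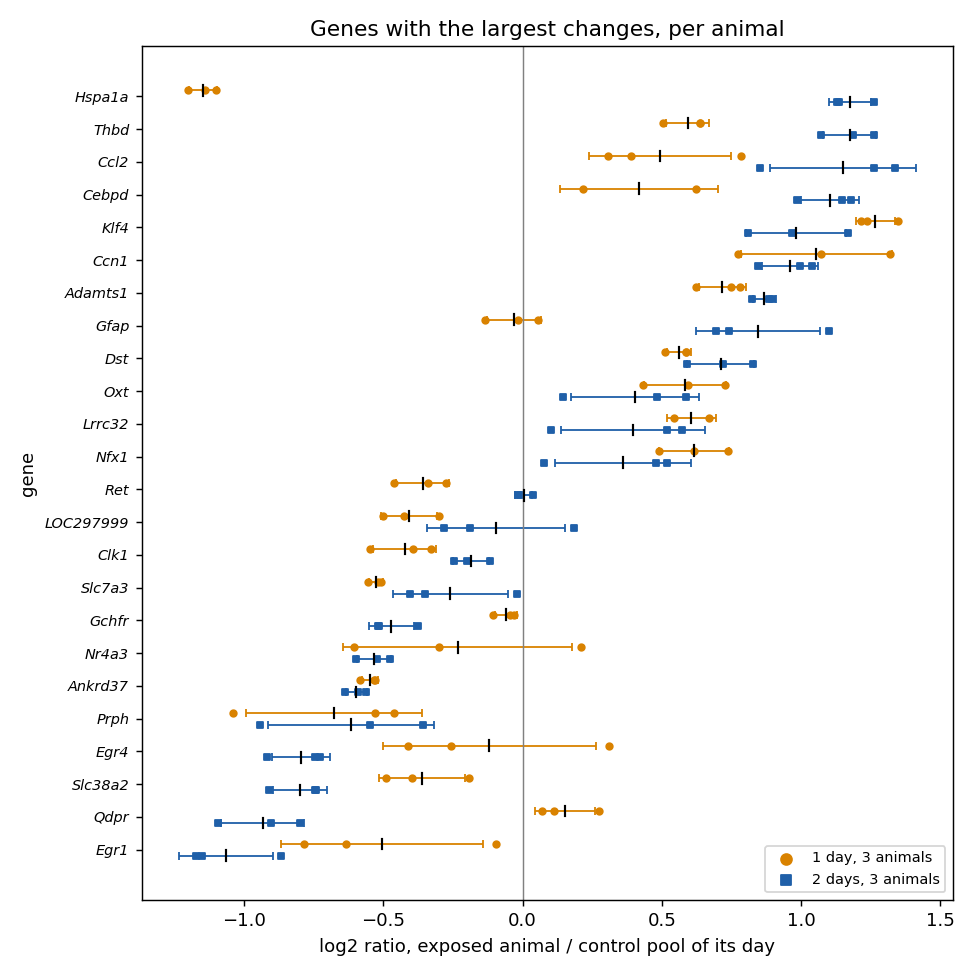
Log2 ratio of exposed over control pool (x axis) for the 24 genes with the largest passing changes in either group (y axis), with 1 point per rat with a value (2 rats for Lrrc32 and Cebpd after 1 day), a black tick at the mean and a bar of 1 SD. Hspa1a lies on opposite sides of 0 after 1 day and 2 days, with all 3 rats of each group on the same side, while Klf4, Adamts1 and Ccn1 lie to the right in both.

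The second question was which transcripts differed after 2 days. Hspa1a, lower after 1 day, rose 2.26-fold (log2 1.18 ± 0.08, n = 3, adjusted p = 1.7e-05). Thbd rose 2.26-fold (1.18 ± 0.10, adjusted p = 3.0e-05), or by 2.14 on the log2 scale in the scanner program's ratios, with its dimmer probe at 0.02 ± 0.04. Ccl2, a chemokine that attracts monocytes, rose 2.22-fold (1.15 ± 0.26, adjusted p = 0.0022), or by 1.84 in the program's ratios, and Cebpd, a transcription factor of the acute phase response, rose 2.15-fold (1.11 ± 0.10, adjusted p = 0.0011). Gfap, the intermediate filament of astrocytes, rose 1.80-fold (0.85 ± 0.22, adjusted p = 0.0017). In all, 1587 probes passed, 734 higher and 853 lower, and of the named genes 380 rose and 269 fell. The median size was 0.17, with 22 rising and 7 falling by more than 1.5-fold.

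The largest fall after 2 days was in Egr1, a neuronal activity-regulated transcription factor, at 0.478 of the pool's level (log2 -1.07 ± 0.17, adjusted p = 0.0038). Qdpr, the enzyme that regenerates tetrahydrobiopterin, the cofactor of monoamine synthesis, was at 0.524 (-0.93 ± 0.15, adjusted p = 0.00038), and Slc38a2 at 0.575 (-0.80 ± 0.10, adjusted p = 0.00084). By the program's ratios Egr4 fell most (-1.19), beyond Egr1 (-1.10). Egr4 had a ratio of -0.80 ± 0.10 here (adjusted p = 0.0081), Prph of -0.62 ± 0.30, Ankrd37 of -0.60 ± 0.04, Nr4a3 of -0.53 ± 0.06 (-0.96 by the program's ratios, adjusted p = 0.0706) and Gchfr, the feedback regulator of GTP cyclohydrolase, of -0.47 ± 0.08, all past the threshold in the fit used here. A second Nr4a3 probe, of another transcript variant, stood at -0.06 ± 0.05 and did not pass. Against the control pool of the other day, an alternative chosen after seeing the data, Gchfr stood at 0.04. Klf4 (0.98 ± 0.18), Ccn1 (0.96 ± 0.10, or 1.54 by the program's ratios) and Adamts1 (0.87 ± 0.04) were again among the largest rises.

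By camera 4 of 36 lists passed after 2 days, all 4 upward. Of 19 measured microglia and macrophage markers, 6 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.00035, or adjusted p = 0.356 with an estimated correlation). They included the complement subunits C1qb (0.46 ± 0.08) and C1qc (0.22 ± 0.06), the adaptor Tyrobp (0.27 ± 0.06) and the Fc receptor Fcgr2b (0.45 ± 0.27). Of 18 reactive astrocyte markers, 4 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.0020, or adjusted p = 0.356 with an estimated correlation). They were Gfap, Tgm2 (0.62 ± 0.10, or 1.37 by the program's ratios), Emp1 (0.74 ± 0.12) and Nes, the intermediate filament nestin (0.47 ± 0.05, or 0.89). Of 17 general astrocyte markers, 4 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.0282, or adjusted p = 0.356 with an estimated correlation). Gfap and Cst3, or cystatin C (0.24 ± 0.06), were among the rises, and the claudin Cldn10 was the 1 that fell (-0.20 ± 0.06). Of 26 oxidative stress and Nrf2 genes, 7 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.0097, or adjusted p = 0.356 with an estimated correlation). Those that rose included Nqo1 (0.27 ± 0.05), the metallothionein Mt1 (0.27 ± 0.06) and Nfe2l2 (0.19 ± 0.02), whose other probe did not pass. Against the control pool of the other day Tyrobp stood at 0.125 and Nfe2l2 at 0.021 (adjusted p = 0.491 and 0.833), and Cst3 at 0.197 and Fcgr2b at 0.383 also missed the threshold (adjusted p = 0.0925 and 0.147). With an estimated correlation 0 lists passed, where 4 of 36 had an unadjusted p under 0.05. By fry, 6 of 36 lists moved on balance one way and 28 changed in either direction. Against the control pool of the other day 0 lists passed, and with arrays of the exposed rat in Cy3 alone 0 passed.

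Immediate early genes moved both ways after 2 days: of 24 measured, 6 rose and 3 fell (7 and 5 adjusted over the list alone), and the list did not pass as a set (camera adjusted p = 0.304). Klf4, Ier2 (0.38 ± 0.05), Klf6 (0.30 ± 0.05), Atf3 (0.26 ± 0.09, or 0.67 by the program's ratios), Jun (0.21 ± 0.03) and Dusp6 (0.17 ± 0.05) rose, while the 3 that fell were Egr1, Egr4 and Nr4a3. Of 19 measured endothelial markers, 0 rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.232). These counts leave out a probe of the listed marker Icam2, which rose by 0.40 ± 0.03 after 2 days (adjusted p = 0.00084). That probe had also risen after 1 day, by 0.42 ± 0.06. The 4 that fell were Itm2a (-0.33 ± 0.11), the blood-brain barrier transporters Slco1a4 (-0.23 ± 0.003) and Slco1c1 (-0.23 ± 0.03), and the drug efflux pump Abcb1a (-0.15 ± 0.04, or -0.24 by the program's ratios). Of 13 genes of sulfide and carbonyl sulfide metabolism, 1 rose, the carbonic anhydrase Car4 (0.13 ± 0.08), and 1 fell, the cysteine dioxygenase Cdo1 (-0.16 ± 0.10), as also adjusted over the list alone (camera adjusted p = 0.628).

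Of the 13 measured genes of the fixed set, 4 passed after 2 days: Hspa1a, Gfap, Egr1 and the stress-induced Gadd45b (0.26 ± 0.01). The 9 that did not included Fos (0.03 ± 0.05), Il1b (0.07 ± 0.05), Hmox1 (0.04 ± 0.01), Nos1 (-0.01 ± 0.08), Vegfa (-0.03 ± 0.14), Ptgs2 (-0.01 ± 0.02), Cox4i1 (0.09 ± 0.09) and Fkbp5 (0.03 ± 0.05). The number of passing probes was 230, 1036 or 891 without animal 6, 16 or 19, and 1036 with the scanner program's ratios. Without animal 6 more were higher than lower (140 and 90), and with median centring 532 were higher and 896 lower. The genes Clk1, Cst3, Egr4, Fcgr2b, Jun, Lrrc32, Mt1, Nfe2l2, Nfx1, Nr4a3, Oxt, Prph and Sult1a1 lost their calls when at least 1 of animals 6, 16, 19, 3 and 9 was left out, at adjusted p values between 0.05 and 0.247. Against the control pool of the other day 892 probes passed, 441 of them among the 1587. The calls of Gadd45b (0.124), Dst (0.289), Lrrc32 (0.236), Nfx1 (0.342), Oxt (0.37) and Prph (-0.442) were lost, at adjusted p values between 0.0554 and 0.188.

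The responses to both durations were set side by side across genes, which are not independent replicates. The mean ratios of the 8950 named genes had a Pearson r of 0.534 and a Spearman rho of 0.437, and a covariance of 0.00393. Unchanged groups simulated against a pool of 3 rats shared by both days gave a median r of 0.500 and a covariance of 0.00185. Against separate pools they gave an r of -0.013, so part of the correlation may come from shared controls if both pools hold the same rats. The covariance above that of a shared pool was 0.00208, while the share of genes with the same sign, 62.3%, lay below the simulated 66.9% of a shared pool (49.9% for separate pools). Of the passing probes, 279 were higher and 219 lower after both durations, where independent lists would share 16.4 and 15.1, and the simulated unchanged groups shared at most 1. The simulated probes were drawn independently of each other, while real probes may move together within a rat or pool. The gaps to the simulated values therefore do not show a response shared by both durations. Klf4, Ccn1, Adamts1, Thbd, Dst, Ier2 and Klf6 rose after both durations, and Prph, Ankrd37, Clk1 and Slc38a2 fell after both. Passing probes of opposite direction numbered 4, of which Hspa1a was the 1 named gene.

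**Figure D2:**
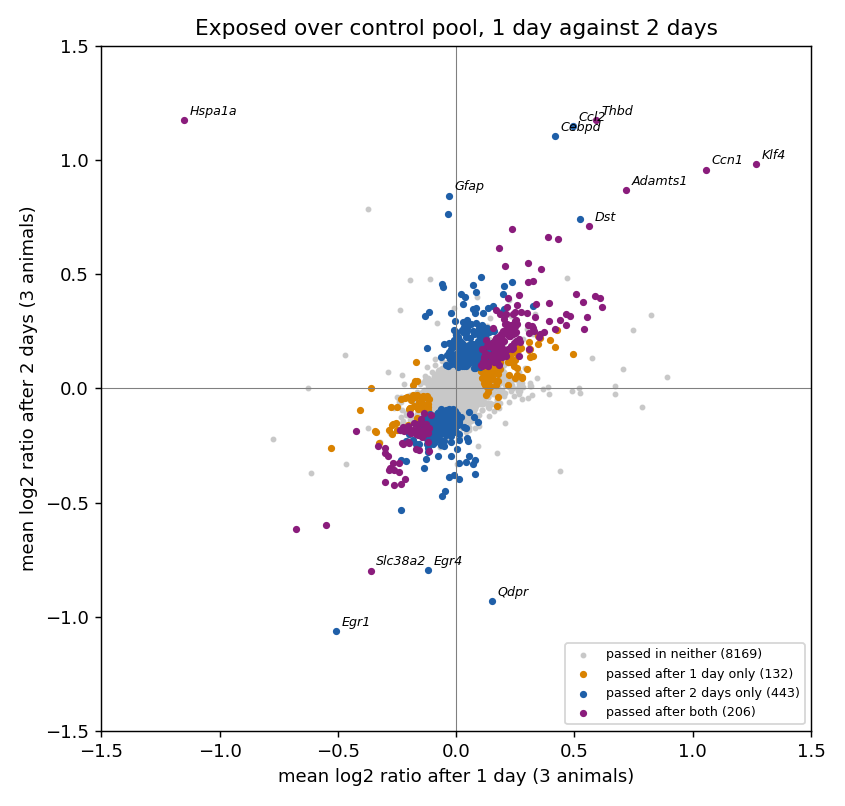
Mean log2 ratio of exposed over control pool after 1 day (x axis) and after 2 days (y axis), with 1 point per named gene and colours for where it passed: 206 genes after both durations, 132 after 1 day only, 443 after 2 days only and 8169 in neither. Passing in one group alone is no test of a difference between them, and Hspa1a stands apart at the upper left.

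The last question was which responses differed between 2 days and 1 day. Hspa1a had the largest difference, at 2.33 ± 0.05 (SE) on the log2 scale (adjusted p = 1.3e-06), from 0.451 to 2.26 times the pool's level. Qdpr differed by -1.09 ± 0.08 (adjusted p = 0.0057), standing at 0.15 ± 0.11 after 1 day, and Thbd by 0.58 ± 0.06 (adjusted p = 0.0261). Tnnc2, the troponin C of fast skeletal muscle, differed by -0.46 ± 0.04 (adjusted p = 0.0166), from 0.08 ± 0.05 to -0.38 ± 0.05. These 4 were the named genes among 9 probes that passed, 5 higher and 4 lower after 2 days. A further 1 was a dimmer probe of Ddc, the aromatic amino acid decarboxylase, chosen after its values were seen (-0.65 ± 0.06, adjusted p = 0.0167). The probe that represents Ddc missed the threshold with a difference of -0.35 ± 0.04. So did Gfap with 0.88 ± 0.11, Tgm2 with 0.44 ± 0.05 (0.892 by the program's ratios) and Gchfr with -0.41 ± 0.05, and each of these 4 had an adjusted p of 0.0506.

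By camera, 7 of 36 lists differed between the durations, and none did with an estimated correlation, where 3 had an unadjusted p under 0.05. Heat shock proteins were higher after 2 days (adjusted p = 0.0019, or adjusted p = 0.485 with an estimated correlation). Only Hspa1a passed among 14, also adjusted over the list alone, and Cryab and Hspa8 differed by 0.37 ± 0.13 and 0.08 ± 0.05 without passing. Microglia and macrophage markers (adjusted p = 0.0019, or adjusted p = 0.497 with an estimated correlation) and reactive astrocyte markers (adjusted p = 0.0019, or adjusted p = 0.485) were higher after 2 days, with 0 members passing and 5 and 2 higher adjusted over the list alone. Immediate early genes were lower (adjusted p = 0.0019, or adjusted p = 0.626 with an estimated correlation), with 0 passing and 2 higher and 8 lower adjusted over the list alone, among them Nr4a1 with a difference of -0.80 ± 0.16. Glucocorticoid response genes were higher (adjusted p = 0.015, or adjusted p = 0.657 with an estimated correlation), with 0 passing and 4 higher adjusted over the list alone. In that list Cebpd, Mt1 and Sult1a1 differed by 0.69 ± 0.12, 0.23 ± 0.05 and 0.52 ± 0.14. Cebpd had values in 2 rats after 1 day, so camera, which used genes with a value in every rat, left it out. Another member, Tsc22d3, was lower than the pool after 2 days (-0.19 ± 0.09, adjusted p = 0.027), and its difference of -0.08 did not pass.

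Markers of neighbouring tissue also moved between the durations. Cerebellar markers were higher after 2 days (mean difference 0.25 and median 0.07 over 12 genes, adjusted p = 0.0227) and meningeal fibroblast markers lower (mean difference -0.32 and median -0.31 over 12 genes, adjusted p = 0.0271). Camera used the 11 of each with a value in every rat, with adjusted p = 0.657 for both with an estimated correlation. No member of either passed, over all probes or adjusted over the list alone. Single values differed widely between rats. Fmod stood at -0.12, 1.38 and 0.75 in animals 2, 3 and 9, and Car8 at 1.14, 0.48 and -0.19 in animals 6, 16 and 19. Grm4 and Slc1a6 differed by 0.18 ± 0.07 and 0.36 ± 0.10, Igfbp2 and Lum by -0.38 ± 0.19 and -0.08 ± 0.04. The pool channels of the 2 days differed in their log2 levels with an SD of 0.133 across 8760 genes, the exposed channels with 0.154, and these differences had an r of 0.845 across genes. These shifts therefore do not separate a difference between the pools from slide lot. Thbd missed the threshold when any 1 of animals 2, 3, 9, 6 and 16 was left out (adjusted p between 0.0797 and 0.154), and Tnnc2 without animal 3, 9, 6 or 16 (between 0.0525 and 0.110). The number of passing probes was 5 without animal 3, 20 without animal 19 and 3 with the scanner program's ratios, by which Qdpr, Tnnc2 and Thbd had adjusted p values of 0.0501, 0.0749 and 0.355.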

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

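The splits of the rats and the test of serotonin neuron markers were set before their results were seen, and the tests of the control pools, of the slide lot, of the heat shock proteins and of the shares of glial cells were chosen only after the result was seen. The genes, probes and lists of this paragraph differed between 2 days and 1 day of exposure by the test of the difference itself. For the lists this was camera with the preset correlation, and none passed with an estimated correlation (adjusted p from 0.485 to 0.657). The differences, 2 days minus 1 day on the log2 scale, were 2.325 for Hspa1a, -1.086 for Qdpr, -0.647 for a dimmer probe of Ddc, -0.456 for Tnnc2 and 0.582 for Thbd. Probes without a gene symbol differed by 1.776 (A_43_P15711), 1.261 (A_42_P567268), 0.92 (A_42_P520133) and -0.444 (A_43_P10539). List means differed by 0.226 for heat shock proteins, 0.081 for microglia and macrophage markers, 0.128 for reactive astrocyte markers, 0.191 for glucocorticoid response genes, 0.251 for cerebellar markers, -0.133 for immediate early genes and -0.323 for meningeal fibroblast markers, with medians in the same order of 0.051, 0.04, 0.043, 0.134, 0.07, -0.016 and -0.307. The 6 rats can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 9 probes and the highest other 0, so that 1 of 10 gave as many, and the real split gave 7 lists and the highest other 7, so that 2 of 10 gave as many. The split with as many lists set animal 2 with animals 16 and 19.

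Hspa1a was lower than the pool in all 3 rats after 1 day and higher in all 3 after 2 days, at mean single-channel levels of 7.74 in exposed rats and 8.89 in the pool on the first day and 9.51 and 8.33 on the second. A difference between the control pools alone is argued against, because the exposed channel itself moved by 1.773 ± 0.053 (SE), against at most 0.973 in any shift shared by both channels of 8759 other genes. A response of similar size shared by heat shock proteins is argued against too: the other 13 had a median difference of 0.043, with an SD of 0.102. Hspa1a was the member with the smallest p, however, and Cryab and Hspa8 differed by 0.37 and 0.08 without passing. A smaller shared response is therefore not decided by this comparison. Against the other day's pool the ratios were smaller, at -0.60 and 0.62, with adjusted p values of 0.0067 and 0.0029, the highest over all 21 alternatives (lowest 3.0e-11 and 2.2e-11), so a part of each change may still belong to the pools. A change with the length of exposure, which the design names, stays open as a hypothesis. The slide lot alone would move both channels of a slide alike, while the pool channel shifted by -0.553 (SD of 0.082 over genes for the difference between channel shifts). The gap between the channels' shifts is the tested difference itself, so it is no separate evidence against the slide lot.

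Gfap and C1qb were higher after 2 days in all 3 rats, by 0.85 and 0.46, and the differences from 1 day, 0.88 and 0.38, missed the threshold (adjusted p = 0.0506 and 0.209). A larger share of astrocytes as the whole cause is argued against for Gfap, since the 16 other astrocyte markers had a median of 0.101 with an SD of 0.112. Gfap was the member with the smallest p, however. Of the 17 markers 10 rose and 1 fell adjusted over the list alone, so a larger share may add a part. For C1qb, the 18 other microglia and macrophage markers had a median of 0.066 with an SD of 0.135. C1qb was the member with the smallest p, and Fcgr2b rose by 0.45. Of the 19 markers 9 rose and 0 fell adjusted over the list alone. A larger share of microglia is therefore not decided by this comparison. The control pool of the second day alone is argued against for both by the ratios against the other pool. These were 0.728 for Gfap (adjusted p = 0.0098, between 1.1e-06 and 0.013 over 21 alternatives) and 0.571 for C1qb (adjusted p = 0.0228, between 5.8e-06 and 0.0415). They compare channels across slides, and shifts shared by both channels of other genes reached 0.973. The second day's pool together with slide lot is therefore not excluded. Raised expression of these genes within glia after 2 days is a candidate explanation that the design leaves untested. The pool and exposed channels shifted by -0.118 and 0.759 for Gfap and by 0.116 and 0.498 for C1qb (SD of the difference over genes 0.082). The gap between the channels is the difference from 1 day itself, which missed the threshold for both genes. These shifts therefore do not decide on the slide lot.

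Ddc, Slc6a4, Gchfr, Qdpr and Gal, 4 genes of monoamine synthesis and transport and the neuropeptide galanin, were lower after 2 days, with a median of -0.448, and were grouped after their values were seen, though only Qdpr and the dimmer Ddc probe passed for the difference and Gal was already lower after 1 day (-0.26, adjusted p = 0.00757). For Ddc, Slc6a4 and Gchfr, a higher level in the second day's pool alone may be the cause. Against the other pool their median was -0.022, within the SD of 0.133 between the pool channels of the days, which holds slide lot too. The dimmer Ddc probe stood at -0.212, outside that SD, and slide lot could hide a change in the exposed rats. The same explanation is argued against for Qdpr, at -0.89 against the other pool, and for Gal, at -0.276. Slide lot enters these ratios too, and shifts shared by both channels of other genes reached 0.973. The second day's pool together with slide lot is therefore not excluded for Qdpr or Gal. Less tissue with serotonin neurons in the exposed rats is not decided by 3 markers not looked at before. These were Fev (-0.08 ± 0.01), Gch1 (0.003 ± 0.12) and Gata2 (0.04 ± 0.06) after 2 days. Their median was 0.003, with an SD of 0.062 between them. Fev was lower in the limma fit without passing (adjusted p = 0.124). How much other cells add to the signals of these markers was not tested, and such signal could hide a fall. Of 9 markers listed, 6 were measured and 0 passed, and a change of Qdpr with the length of exposure stays open.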

How the results depend on the processing

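The comparison with the control pool of the other day was chosen only after the result was seen, and all other settings were fixed before. Passing probes after 1 day (809, of them 452 higher and 357 lower) numbered 337 with an offset of 0 (227 higher, 110 lower, 67.4% higher), 367 with the scanner program's ratios and 367 with the series matrix (each 243 higher and 124 lower), 497 with median centring and 515 in a fit of this group alone. They numbered 1577 with the rat as a random block, 1904 with a dye term too, 2653 with the exposed rat in Cy5 only and 2940 in Cy3 only. After 2 days (1587) the counts were 994, 1036 and 1034 with the offset of 0, the program and the matrix, 2569 with the block and dye term, 4084 and 3006 with Cy5 and Cy3 only, and 892 with the other pool. For 2 days against 1 day (9, of them 5 higher) they were 5 (4 higher, 1 lower), 3 and 3 (all higher), 14 (6 and 8) with median centring, 16 (8 and 8) with probes above background on all arrays, 158 with the block and 184 with the dye term. Leaving out 1 rat gave 57 to 905, 230 to 1678 and 5 to 20 probes, the lowest without animals 3, 6 and 3. Lists passing after 1 day (0) numbered 3 without background subtraction, 2 with median centring, 2 with outlier spots kept, 4 with the block, 5 with the dye term and 5 with the group alone. After 2 days (4) they numbered 8 with either block and 0 with Cy3 only, the other pool or an estimated correlation, and for 2 days against 1 day (7) 0 with an estimated correlation. Leaving out 1 rat gave 0 to 6, 4 to 6 and 3 to 7 lists. The r of 0.534 was 0.487, 0.482 and 0.482 with the offset of 0, the program and the matrix, 0.642 with Cy5 only, 0.674 with Cy3 only and 0.459 to 0.567 with 1 rat left out. Single orientations keep the dye effect, whose SD was 0.073, and the block fits count arrays, whose correlation within a rat was -0.221, or 0.255 with the dye term. For the other settings the cause was not tested. Of named genes, values that changed sign while past the threshold in either setting were those of Gchfr after 2 days with the other pool (0.036), Hspa8 after 1 day with Cy5 only (-0.147) and Lum after 2 days with Cy5 only (0.184). Named genes that passed kept direction and call in 276 of 294 values under planned settings after 1 day, 487 of 518 after 2 days and 41 of 52 for the difference. With 1 rat left out they did so in 97 of 124, 190 of 218 and 15 of 24, and with the other pool in 15 of 21 and 26 of 37. Aquantile moved no ratio, and the series matrix holds the program's ratios, so neither adds a separate check to the counts under planned settings. The slide or scan date as a block was not run because each slide held 1 array and 1 date held all. No paired analysis was possible because the groups share no replicate number. Weak signal limits dim genes: Thbd after 1 day was 0.59 with an offset of 50, 1.24 with an offset of 0 and 1.53 by the program.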

Other observations

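The tests of amino acid response genes and of YAP and SRF targets were chosen only after the result was seen, and the genes and probes named here were picked after their values were seen. Of 19 neuron markers 1 rose and 1 fell after 1 day (2 and 5 adjusted over the list alone) and 2 rose and 1 fell after 2 days (2 and 1), and the list did not pass (camera adjusted p = 0.287 and 0.791). Nefh, the heavy neurofilament subunit, rose by 0.43 ± 0.16 after 1 day and 0.66 ± 0.14 after 2 days, while Gap43, a growth cone protein, stood at -0.28 ± 0.03 and -0.35 ± 0.08, and all 4 values passed. Of 16 oligodendrocyte markers 0 changed after 1 day and 2 rose after 2 days (3 adjusted over the list alone), Aspa (0.34 ± 0.18) and Mal (0.32 ± 0.05), with a camera adjusted p of 0.0564 (adjusted p = 0.666 with an estimated correlation). Their differences from 1 day were 0.45 for both and missed the threshold (adjusted p = 0.205 and 0.0807). Of 14 circadian clock genes 0 changed after 1 day (1 rose adjusted over the list alone) and 2 fell after 2 days (also 2 adjusted over the list alone), when the list had a median of 0.004, a mean of -0.025 and a camera adjusted p of 0.628, downward. Those were Per2 and Dbp, at -0.29 ± 0.13 (-0.45 by the scanner program's ratios) and -0.20 ± 0.08, both past the threshold. Of 26 genes of GABA and glycine transmission 1 rose and 1 fell after 1 day, also adjusted over the list alone (camera adjusted p = 0.912). Gabrb1, a receptor subunit for GABA, was lower after 1 day (-0.24 ± 0.02), and passed then but not after 2 days (-0.05 ± 0.13), with a difference of 0.19 that did not pass (adjusted p = 0.469).

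Of 32 genes of vascular tone and vessel mediators 4 rose and 1 fell after each duration (6 and 1, and 7 and 1, adjusted over the list alone), and the list did not pass (camera adjusted p = 0.270 and 0.240). Of these F3, the tissue factor that starts coagulation, rose by 0.20 ± 0.03 after 1 day and 0.21 ± 0.06 after 2 days, and Kdr, a receptor of VEGF, rose by 0.32 ± 0.10 after 1 day. After 2 days Kdr stood at 0.14 ± 0.05 without passing, and its difference did not pass (adjusted p = 0.445). Gucy1a1, a subunit of the nitric oxide receptor, stood at -0.33 ± 0.06 and -0.25 ± 0.09, past the threshold after both. Outside that list, Vcam1 fell after 2 days (-0.25 ± 0.05), when Ccl2 rose. Podxl, podocalyxin, rose by 0.70 ± 0.06 after 2 days and by 0.24 ± 0.09 after 1 day, and its difference of 0.46 missed the threshold (adjusted p = 0.0506).

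Lower activity of the amino acid response was considered for the falls of Slc38a2 and Slc7a3, as a hypothesis. The 19 measured genes of that response had medians of -0.003 after 1 day and 0.002 after 2 days, with SDs of 0.143 and 0.129. Members went both ways, so the test does not decide. Of these, the amino acid transporters Slc7a1 and Slc7a5 stood at -0.31 ± 0.09 and -0.24 ± 0.13 after 2 days and passed, while Pck2 rose by 0.16 ± 0.04. Higher activity of the YAP and SRF transcription factors was considered for Ccn1. The 15 other targets had medians of 0.024 after 1 day and 0.022 after 2 days, with SDs of 0.212 and 0.131, and Ccn2 stood at 0.82 after 1 day without passing (adjusted p = 0.061), so this may be open too.

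The probe A_43_P15711, of a sequence without a gene symbol, changed in the same way as Hspa1a, at -0.77 ± 0.06 after 1 day and 1.01 ± 0.13 after 2 days, past the threshold in both. The probe A_42_P567268 stood at 1.53 ± 0.12 after 2 days, past the threshold. Oxt, Nfx1 and Lrrc32 each had their lowest value in animal 16, at 0.14, 0.08 and 0.10, against 0.43 to 0.74 in the other rats with a value. In animals 2, 3, 9, 6 and 19 Oxt stood at 0.726, 0.595, 0.433, 0.586 and 0.482. Nfx1 stood at 0.739, 0.616, 0.489, 0.52 and 0.479 in the same rats. Whether these probes report separate transcripts was not tested. Among the 8760 genes with a value in every rat, the pool channel differed between the days by more than 1.5-fold in 26. In 24 of these the exposed channel differed by more than 1.5-fold in the same direction, among them Slc47a1, whose level was 0.97 higher on the second day in both channels. Such shared shifts do not separate a difference between the pools from slide lot.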
